A study of Mus musculus with 24 samples.

How the data were processed

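RNA was measured by bulk RNA-seq in mammary epithelial cells of pubertal mice, in 24 libraries that form 12 groups of 2. Per the labels' protocols, mammary tissue was separated by microdissection into ducts and terminal end buds (TEBs, the growing tips of the pubertal ductal tree). Lineage-negative EpCAM+ cells were then sorted by flow cytometry into a basal gate (high CD29) and a luminal gate (low CD29). The luminal gate was further divided by a fluorescent reporter: GFP in mice carrying an Elf5-rtTA-IRES-GFP allele, and YFP in mice carrying PR-cre with a Rosa26 lox-stop-lox eYFP allele. The basal gate was sorted in both mouse models. Total RNA was extracted with a miRNeasy kit, treated with DNase and made into libraries with the TruSeq RNA Library Prep Kit v2, which does not mark strand. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 2 libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical in part. The column names of the counts repeat the same model, replicate number and tissue across the sorted gates. Libraries of different gates may therefore come from the same preparation, and sample sizes counted over gates are numbers of libraries, not of animals.

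The deposited files hold whole-number counts per gene, one column per library and an identical table for the whole series, which differed from the single files in 0 values. Per the submitters' processing notes, featureCounts was used with the mm10 genome build; the aligner, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Each table lists 27179 genes by Entrez identifier. Symbols were taken from a RefSeq gene table for 25275 of them and from GENCODE tables for 18; 1886 identifiers, with 1.22% of all counts, stayed without a symbol and are named by the word Entrez and their number. The 13 mitochondrially encoded protein genes carry their GENCODE symbols. The tables hold no row of unassigned reads. Total counts per library ran from 31.3 to 52.5 in units of 1e6, and a count of 3 corresponded to between 0.058 and 0.097 CPM (counts per 1e6 counts). Floors are set by read counts alone. The reads carry no molecular identifiers, so amplified copies of a molecule are not told apart. The replicate libraries of each group differed by more than sampling noise (chi-square per degree of freedom from 18.0 to 174.5 over genes), so no library was counted as a duplicate.

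Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the 12 groups (minimum count 10, minimum total count 15), which left 18109 genes. Libraries were scaled by the trimmed mean of M-values (TMM). One robust quasi-likelihood model with a mean for each of the 12 groups was fitted to all 24 libraries, with 12 residual degrees of freedom, because groups of 2 give little information on spread. Each comparison was a contrast of group means, tested with edgeR's quasi-likelihood F-test, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. Every adjusted p of a gene given in the text comes from this test unless another tool is named. Contrasts averaged groups on the log2 scale, so a fold change over several groups need not equal the ratio of the mean CPM values printed beside it. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. In contrasts that average several groups, the test returned a p near 1 beside a fitted change of over 2 on the log2 scale for some genes, each of which had a compared group with no counts (from 114 to 913 genes per contrast, and 0 in the 4 single gates); such genes were counted as not called. CPM values use the TMM-scaled library sizes and are given as mean ± SD over libraries. For genes with a group at 0 counts the fitted fold change depends on the prior count, and CPM values or a bound against 3 counts over the group are given instead.

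A total of 43 gene lists (cell type markers, pathways and markers of cells outside the gates) were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 43 lists of a contrast. The same test with the correlation estimated from the data called 9 of the 387 list tests over 9 contrasts: 7 in basal against luminal, and the interferon list in the luminal TEB contrast and in the luminal GFP-negative gate. Where a list's call is lost with the estimated correlation, that adjusted p is printed. The member counts "adjusted over the list alone" use p-values adjusted within the list. A list of 12 keratinocyte genes and a second list to check it were added after the data were seen. Genes named by the rule are the 10 (main contrasts) or 5 (single gates, interactions and the model comparison) with the largest log2 fold change in each direction among called genes with an average log2 CPM of at least 3 and non-overlapping libraries (for the luminal TEB contrast, all 4 gates moving the same way; for interactions and models, no such condition), passing over predicted genes; members of the lists may be named besides. Genes with near-identical copies, among them ribosomal protein genes with processed pseudogenes, and overlapping or antisense genes are uncertain, since the counting of shared reads is not known.

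The pipeline was tested on simulated counts for 18109 genes with 200 genes changed. For the basal TEB contrast it recovered 74.5% of 2-fold and 90.0% of 4-fold changes, for the luminal TEB contrast 82.5% and 94.0%, for a single gate (GFP-positive) 47.5% and 82.5%, and for GFP-positive against GFP-negative 77.0% and 90.5%. Between 2.5% and 6.8% of calls were false in these simulations. These rates need not hold for the real counts, where more genes were called than the 200 changed here. Spread between real replicates was also uneven (chi-square per degree of freedom from 18 to 174.5). The GFP-negative, YFP-positive and YFP-negative gates were not simulated. In the GFP-negative gate 3351 genes passed, but 105 in a fit of its groups alone, so its false calls are not known from this test. The alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors (RLE) in edgeR, 2 other filters, a fit of the compared groups alone, a replicate block within each model, leaving out each library in turn and, chosen after seeing the data, leaving out the 2 libraries with keratinocyte transcripts.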

Results

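RNA was measured in 24 libraries of sorted mammary epithelial cells from pubertal mice, in 12 groups of 2. The groups cross the tissue of origin, mature ducts or terminal end buds (TEBs), with 6 sorted populations. These were the basal cells of the Elf5 reporter model, the basal cells of the PR-cre model, and the luminal GFP-positive, GFP-negative, YFP-positive and YFP-negative cells. Total counts per library ran, in units of 1e6, from 31.3 in luminal YFP-negative duct replicate 2 to 52.5 in luminal GFP-positive duct replicate 1, and between 16232 and 18343 genes had at least 1 count. The most abundant transcript was the mitochondrial mt-Co1 in most libraries, with between 1.04% and 1.58% of the counts. In GFP-positive ducts it was Trf, the iron carrier transferrin, with 3.88% and 2.09%. Across genes, the replicates of a group correlated at between r = 0.916 (GFP-negative ducts) and 0.984 (YFP-positive TEBs) in log2 CPM.

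The first principal component held 47.4% of the variance and set the 8 basal libraries (from -195.81 to -172.48) apart from the 16 luminal libraries (from 33.12 to 141.38). The next component held 15.7% and followed the reporters within the luminal gate. GFP-positive libraries lay beside YFP-negative libraries, and GFP-negative beside YFP-positive ones.

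**Figure D1:**
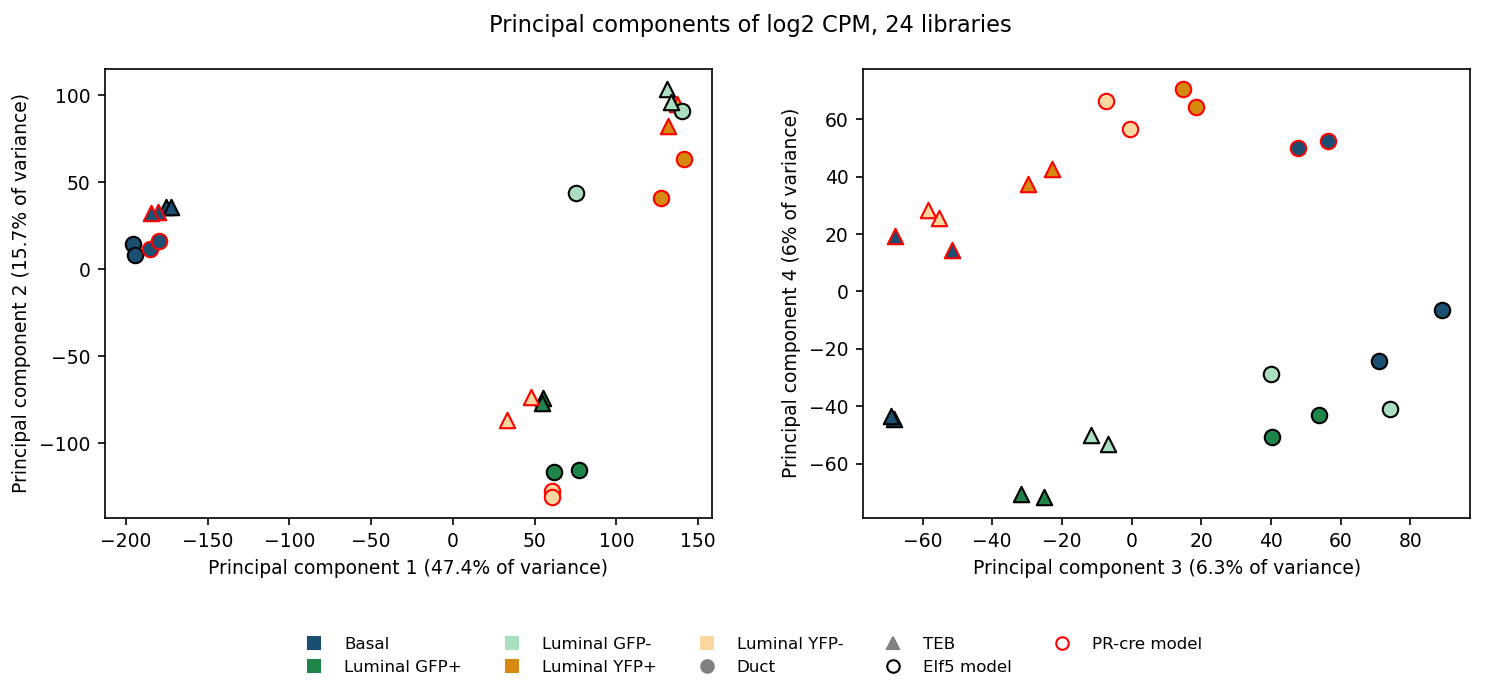
Each point is a library, placed by its scores on the principal components of log2 CPM, with the percent of variance on each axis; colours mark the sorted population and shapes the tissue. Basal libraries lie at or below -172.48 on the axis with 47.4% of the variance, and luminal libraries at or above 33.12.

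The genes behind the reporters and the gates were read in every library as a check of the labels. Elf5, an ETS factor of the luminal progenitor lineage that drives the GFP reporter, stood at 1596 ± 86.4 CPM in GFP-positive ducts and 728.0 ± 43.2 in GFP-positive TEBs (mean ± SD, n = 2 each). Every GFP-negative library had between 26.9 and 68.2 CPM. Pgr encodes the progesterone receptor, and the PR-cre allele switches on YFP from the Rosa26 allele. Pgr stood between 332 and 476 CPM in YFP-positive libraries and between 13.2 and 39.4 CPM in YFP-negative libraries. Itgb1, which encodes CD29, lay between 1269 and 1574 CPM in basal and between 497.7 and 712.8 CPM in luminal libraries. Epcam lay between 185.7 and 334.1 CPM in basal and between 1062 and 1800 CPM in luminal libraries. No library's values for these 4 genes went against its label.

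**Figure D2:**
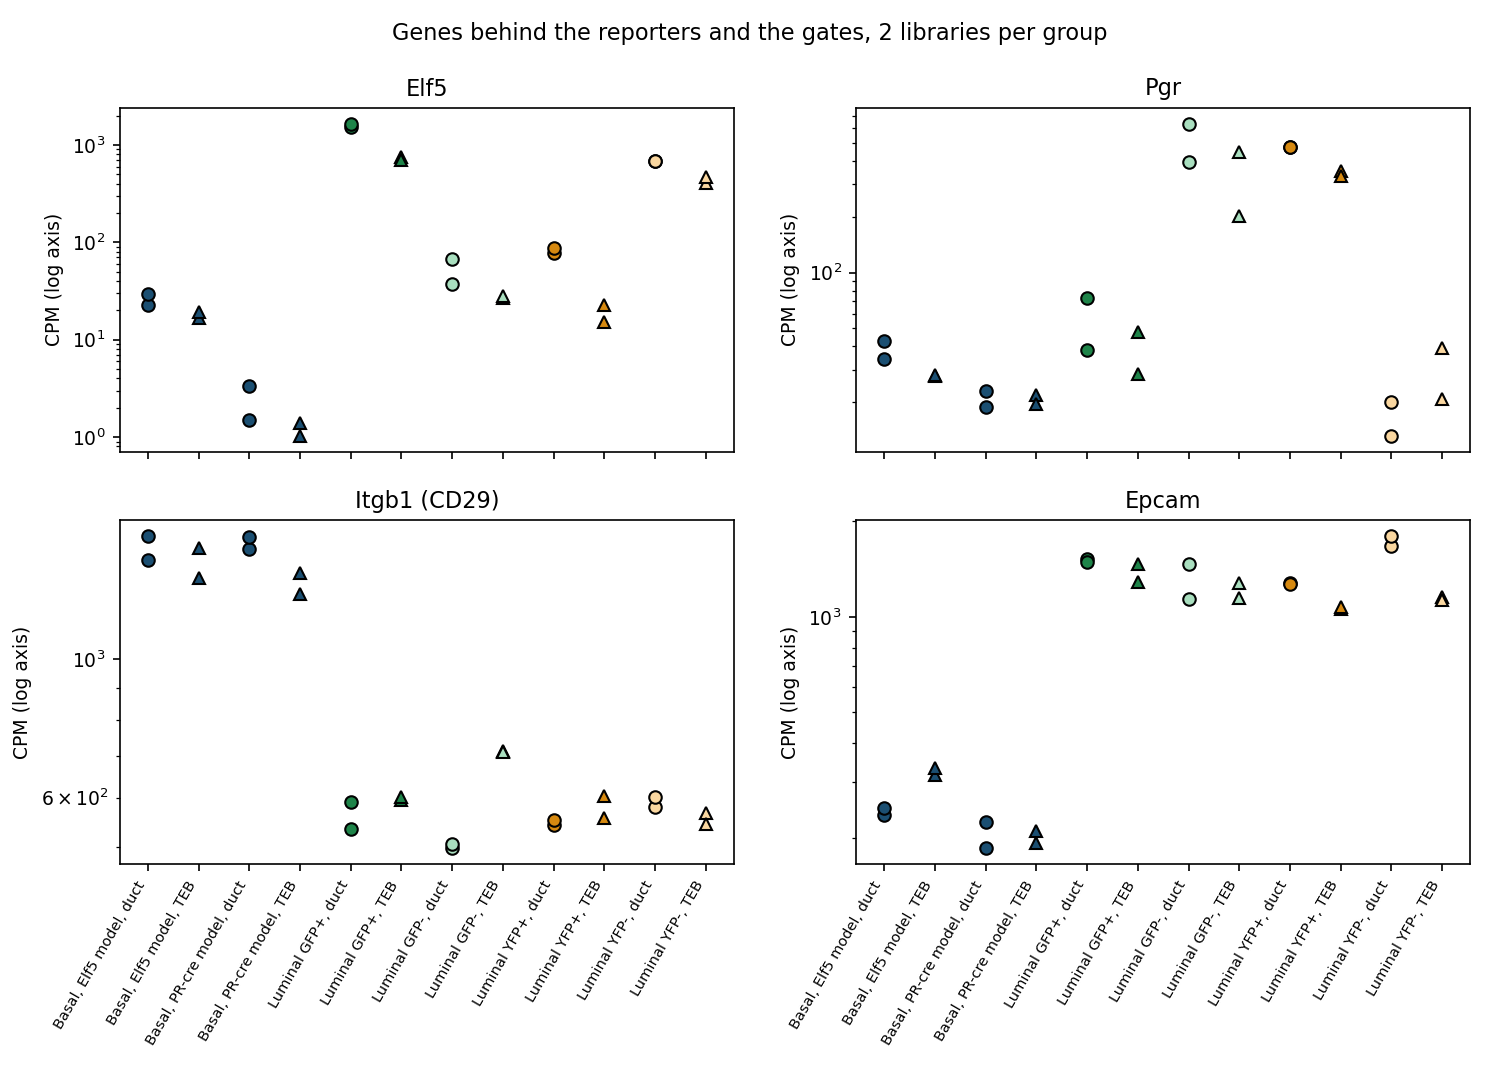
CPM on a log axis of Elf5, Pgr, Itgb1 (CD29) and Epcam in each library, with the 12 groups on the horizontal axis and circles for ducts and triangles for TEBs. Elf5 lies at 1596 CPM on average in GFP-positive ducts, and Itgb1 is at or above 1269 CPM in all basal and at or below 712.8 CPM in all luminal libraries.

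In luminal GFP-negative duct replicate 2, genes of stratified skin epithelium were abundant. A list of 12 keratinocyte genes summed to 3088.1 CPM there, against 11.4 CPM in its replicate. Krt1, Krt10, Krt14 and Krt5 stood at 669.5, 990.9, 1115 and 1962 CPM, against 1.85, 2.13, 3.02 and 4.93 CPM in the replicate. The same list summed to 619.7 CPM in luminal YFP-negative TEB replicate 2 and 73.8 CPM in its replicate, and to between 4.2 and 42 CPM in the other 21 libraries. Among the latter, YFP-negative duct replicate 2 had 25.5 CPM against 4.8 CPM in its replicate, with Krt1 at 3.62 and 0.35 CPM. A fit without GFP-negative duct replicate 2 and YFP-negative TEB replicate 2 therefore leaves lower levels of these transcripts in the YFP-negative gate.

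**Figure D3:**
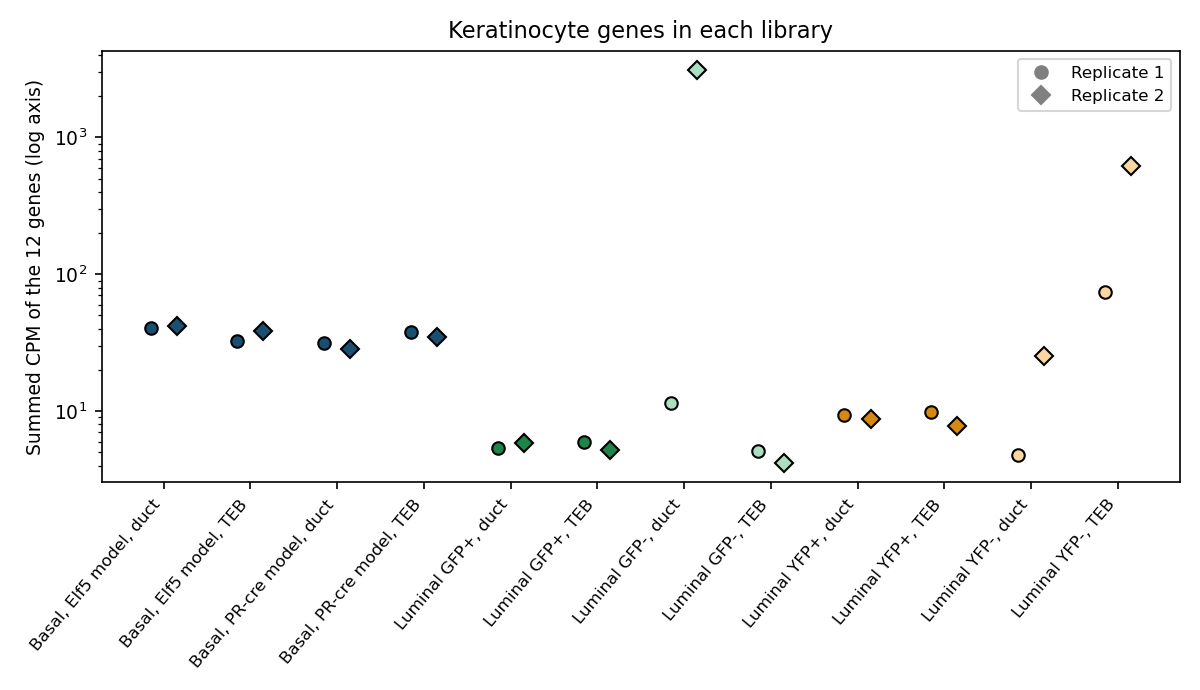
Summed CPM of 12 keratinocyte genes in each library, on a log axis, with the 12 groups on the horizontal axis and circles and diamonds for replicates 1 and 2. GFP-negative duct replicate 2 lies at 3088.1 CPM and YFP-negative TEB replicate 2 at 619.7 CPM, above the 73.8 CPM of the next library.

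The basal TEB and duct comparison asked how cells of the basal gate differ between the growing tip and the mature duct. The gate was not sorted further, so the cap cells of the tip were not separated from its other basal cells. Both mouse models entered the comparison, with 4 libraries per tissue. Basal cells of TEBs expressed more cell cycle and cholesterol synthesis genes, and fewer contractile, luminal keratin and immediate early genes, than basal cells of ducts. Camera at the preset correlation called 16 of 43 lists (26 with fry), and none of them kept its call with an estimated correlation. Without the 2 libraries with keratinocyte transcripts, 11 of the 16 kept their calls. A total of 7902 of 18109 genes passed the test, 3781 higher and 4121 lower in TEBs. Of these, 1141 were more than 2-fold higher and 1869 more than 2-fold lower.

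All 24 measured G2 and M phase genes rose in basal TEB cells, with a median log2 fold change of 2.44. Ccnb1, a mitotic cyclin, rose 7.40-fold (log2 2.89 ± 0.32 SE), and Top2a, which untangles replicated DNA, rose 6.02-fold (2.59 ± 0.46). The proliferation marker Mki67 stood at 669.2 ± 164.6 CPM in TEBs and 126.6 ± 48.97 in ducts (SD, n = 4 each). Of 24 S phase genes, 20 rose and 4 were not called. Both counts were unchanged when adjusted over the list alone. The adjusted p was 6.11e-12 for G2 and M phase and 4.05e-06 for S phase, against adjusted p = 0.474 and 0.598 with an estimated correlation.

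Of 18 cholesterol synthesis genes, 16 rose and none fell (17 when adjusted over the list alone; adjusted p = 1.04e-12, and adjusted p = 0.147 with an estimated correlation). Msmo1, a sterol oxidase of the pathway, rose 4.19-fold (log2 2.07 ± 0.14). Of 21 oxidative phosphorylation genes, 14 rose and none fell, over all genes as well as adjusted over the list alone, with a median log2 fold change of 0.28 (adjusted p = 0.00626, and adjusted p = 0.598 with an estimated correlation).

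The contractile genes of smooth muscle fell. Of 14, 13 fell and 1 was not called, also when adjusted over the list alone (median log2 fold change -2.10, adjusted p = 1.92e-08, and adjusted p = 0.165 with an estimated correlation). Myh11, smooth muscle myosin, was 6.34-fold lower (log2 -2.66 ± 0.24), the oxytocin receptor Oxtr 8.52-fold lower (-3.09 ± 0.45), Lmod1 8.08-fold lower (-3.01 ± 0.29) and smooth muscle actin Acta2 2.19-fold lower (-1.13 ± 0.16). Acta2 nevertheless stood at 4583 ± 1321 CPM in TEBs. Of 14 luminal keratin and identity genes, 9 fell and none rose (9 fell and 1 rose when adjusted over the list alone; adjusted p = 8.01e-07, and adjusted p = 0.165 with an estimated correlation). Krt18 was 8.25-fold lower (-3.04 ± 0.19) and Krt19 4.33-fold lower (-2.12 ± 0.19).

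Basal identity genes went both ways: 2 rose and 5 fell of 14, over all genes as well as adjusted over the list alone, and the list was not called (adjusted p = 0.727). Ngfr, a nerve growth factor receptor, rose 10.8-fold (log2 3.43 ± 0.50). The basal keratin Krt14 stood at 520.6 ± 201.0 CPM in TEBs and 3274 ± 305.4 in ducts, with log2 -2.71 ± 1.02 and adjusted p = 0.0456. Leaving out any single basal library ended that call (adjusted p up to 0.138, without basal PR-cre TEB replicate 1), and leaving out the 2 libraries with keratinocyte transcripts, which widen the spread of Krt14, gave adjusted p = 1.4e-06. Krt5 stood at 732.5 ± 68.5 and 2623 ± 467.9 CPM and was not called (adjusted p = 0.193, and 0.0105 without those 2 libraries).

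Of 19 immediate early genes, which respond to growth factors and to stress, 16 fell in basal TEB cells and none rose, also when adjusted over the list alone (median log2 fold change -1.81, adjusted p = 8.78e-16, and adjusted p = 0.165 with an estimated correlation). Fos stood at 1140 ± 456.6 CPM in TEBs and 7794 ± 1536 in ducts, 7.27-fold lower (log2 -2.86 ± 0.19). Socs3, a feedback inhibitor of cytokine signalling, was 9.11-fold lower (-3.19 ± 0.15). Among 13 heat shock genes, 9 fell and 2 rose, and among 18 NF-kB and chemokine genes, 9 fell and none rose, with identical counts adjusted over each list alone. Both lists had adjusted p = 0.0124, against adjusted p = 0.598 and 0.502 with an estimated correlation. Icam1 was 5.33-fold lower (-2.42 ± 0.22) and Cxcl1 4.62-fold lower (-2.21 ± 0.40). Of 19 junction and polarity genes, 8 fell and 2 rose (9 and 2 when adjusted over the list alone; adjusted p = 0.0146, and adjusted p = 0.474 with an estimated correlation).

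Growth factor signalling genes of basal TEB cells included Nrg1, an ERBB ligand, 6.05-fold higher (log2 2.60 ± 0.36), and its receptor Erbb3, 5.63-fold higher (2.49 ± 0.09). Etv4 and Etv5, ETS factors downstream of FGF receptors, rose 5.49-fold (2.46 ± 0.25) and 3.02-fold (1.59 ± 0.18). The EGF family list (6 rose and 2 fell of 13) and the FGF receptor list (8 rose and 3 fell of 16) had adjusted p = 0.0446 and 0.0282, with identical counts adjusted over each list alone. Their calls were lost with an estimated correlation (adjusted p = 0.245 and 0.367) and in 9 and 3 of the 12 alternatives, where adjusted p reached 0.139 and, without basal PR-cre duct replicate 2, 0.0584. Without the 2 libraries with keratinocyte transcripts adjusted p was 0.0965 and 0.0536.

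The genes with the widest change by the naming rule included Adam23, 32.3-fold higher (log2 5.01 ± 0.38), the imprinted Mest, 17.7-fold (4.14 ± 0.18), the nuclear pore gene Nup210, 15.9-fold (3.99 ± 0.12), Col8a1, 19.6-fold (4.29 ± 0.44), and the proprotein convertase Pcsk6, 14.7-fold higher (3.88 ± 0.25). The milk protein gene Csn3 rose 23.9-fold (4.58 ± 0.42), although 8 of the 16 milk genes fell and the list was not called (adjusted p = 0.117). On the lower side were the glutamate receptor gene Grik3, 138-fold lower (-7.11 ± 0.46), the protease inhibitor Slpi, 115-fold lower (-6.85 ± 0.54), the sodium channel gene Scn7a, 47.1-fold lower (-5.56 ± 0.48), and Tspan8, 25.9-fold lower (-4.69 ± 0.50). Glycam1, an endothelial and milk mucin, stood at 0.0269 CPM in TEBs and 56.8 ± 60.7 in ducts. Kit, a receptor tyrosine kinase of luminal progenitors, rose from 6.45 ± 1.28 to 71.1 ± 12.3 CPM (log2 3.47 ± 0.54, adjusted p = 0.000151).

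In the basal gate, 5 of 17 immune and 9 of 14 endothelial and pericyte genes fell in TEBs and none rose (4 and 10 adjusted over each list alone), although the lists were not called (adjusted p = 0.247 and 0.0863). Fibroblast markers were not called either (2 of 14 rose and 2 fell, also adjusted over the list alone; adjusted p = 0.749), at between 672.3 and 1214.8 CPM in ducts and between 638.4 and 1627.8 CPM in TEBs. The immune list summed to between 17.6 and 42.5 CPM in duct libraries and between 5.8 and 10.9 CPM in TEB libraries, and the endothelial and pericyte list to between 33.2 and 157.5 and between 19.3 and 40.8 CPM. The leukocyte gene Ptprc stood at 2.90 ± 3.12 CPM in ducts and 0.0855 ± 0.109 CPM in TEBs, and the endothelial gene Pecam1 at 12.1 ± 12.1 and 2.01 ± 0.803 CPM. In the same direction, the MHC class II gene Cd74 stood at 13.6 ± 6.66 and 1.71 ± 1.02 CPM. Of 9 MHC class II genes, 4 fell (5 when adjusted over the list alone; adjusted p = 0.0282, 0.0539 without basal Elf5-model TEB replicate 2, 0.0536 without the 2 libraries with keratinocyte transcripts, and adjusted p = 0.165 with an estimated correlation).

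The luminal TEB and duct comparison averaged the 4 luminal gates, with 8 libraries per tissue, and asked what the luminal cells of TEBs share against those of ducts. Luminal TEB cells expressed more cell cycle, interferon response and cholesterol synthesis genes, and fewer milk protein, luminal progenitor and immediate early genes. Of the 10 lists called at the preset correlation, the interferon list alone kept its call with an estimated correlation. A total of 7003 genes passed the test, 3629 higher and 3374 lower in TEBs, among them 864 more than 2-fold higher and 839 more than 2-fold lower. In each of the 4 gates separately, 281 genes were higher and 153 lower in TEBs, where independent lists of those sizes would share 0.9 and 0.5.

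All 24 S phase and all 24 G2 and M phase genes rose in luminal TEB cells, also when adjusted over each list alone (median log2 fold changes 1.57 and 2.30). Ccnb1 rose 5.85-fold (log2 2.55 ± 0.22), and Mki67 rose from 130.3 ± 58.5 to 661.7 ± 319.1 CPM (2.23 ± 0.31; SD, n = 8 each). The lists had adjusted p = 2.15e-17 and 1.62e-22, against adjusted p = 0.29 and 0.258 with an estimated correlation. Of 18 cholesterol synthesis genes, 15 rose and none fell (16 when adjusted over the list alone; adjusted p = 7.05e-08, and adjusted p = 0.169 with an estimated correlation).

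Of 18 interferon response genes, 15 rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 1.81. The antiviral genes Oas1a and Usp18 rose 6.43-fold (log2 2.68 ± 0.15) and 5.41-fold (2.44 ± 0.15), and the ubiquitin-like modifier Isg15 rose 4.28-fold (2.10 ± 0.13). The list had adjusted p = 7.49e-21, and its call held with an estimated correlation (adjusted p = 0.0428).

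Milk protein and secretory genes, which are markers of alveolar differentiation, fell in luminal TEB cells: 11 of 16 fell and none rose (12 when adjusted over the list alone; median log2 fold change -2.86). Lalba, a subunit of lactose synthase, was 25.1-fold lower (log2 -4.65 ± 0.39), the milk fat globule gene Btn1a1 25.2-fold lower (-4.65 ± 0.29), Trf 9.07-fold lower (-3.18 ± 0.24) and Csn3 4.55-fold lower (-2.19 ± 0.27). The list had adjusted p = 2.32e-10, and adjusted p = 0.0905 with an estimated correlation. Of 14 luminal progenitor genes, 9 fell and none rose (10 when adjusted over the list alone; adjusted p = 9.13e-05, and adjusted p = 0.423 with an estimated correlation). Elf5 was 2.32-fold lower (-1.21 ± 0.14) and the Notch target Hey1 6.21-fold lower (-2.63 ± 0.28).

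Of 19 immediate early genes, 17 fell in luminal TEB cells and none rose, also when adjusted over the list alone (adjusted p = 6.3e-25, and adjusted p = 0.0731 with an estimated correlation). Fos stood at 1535 ± 762.4 CPM in TEBs and 6493 ± 3042 in ducts, 4.50-fold lower (log2 -2.17 ± 0.13), and the stem cell factor Klf4 was 2.86-fold lower (-1.52 ± 0.05). Of 9 MHC class II genes, 7 fell, also adjusted over the list alone, at low levels (Cd74 at 1.16 ± 0.666 and 4.34 ± 2.29 CPM; adjusted p = 0.00568, and adjusted p = 0.075 with an estimated correlation). Ptprc fell with them, from 1.08 ± 0.502 to 0.0963 ± 0.0742 CPM, and the immune list summed to between 6.2 and 20.3 CPM in luminal ducts and between 3.1 and 10.7 CPM in luminal TEBs (2 of 17 genes fell, also adjusted over the list alone; adjusted p = 0.467). The hormone-sensing luminal list was not called (3 rose and 1 fell of 14, with 2 and 1 adjusted over the list alone; adjusted p = 0.771). The receptor genes Esr1 and Pgr had log2 fold changes of 0.19 ± 0.11 (adjusted p = 0.223) and -0.21 ± 0.21 (adjusted p = 0.497).

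Genes named by size of change in all 4 luminal gates included Has2, which makes hyaluronan, 12.4-fold higher (log2 3.64 ± 0.33), the interferon gene Oas2, 9.50-fold (3.25 ± 0.32), Ptprn, 8.54-fold (3.10 ± 0.27), and Padi3, 8.42-fold higher (3.07 ± 0.18). The imprinted growth regulator RNA H19 stood at 35.2 ± 36.4 CPM in TEBs and 3.76 ± 6.04 in ducts, with no count in a duct group. The activin antagonist Fst rose 8.71-fold (3.12 ± 0.51; 2.34 without luminal YFP-negative TEB replicate 2). Apod, a lipid carrier, was 50-fold lower (-5.64 ± 0.39) and the mucin-like Fcgbp 24.1-fold lower (-4.59 ± 0.44; -3.99 without luminal GFP-negative duct replicate 2). The peptide hormone gene Cck was 29.2-fold lower (-4.87 ± 0.41; -5.94 without luminal GFP-negative TEB replicate 2).

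**Figure D4:**
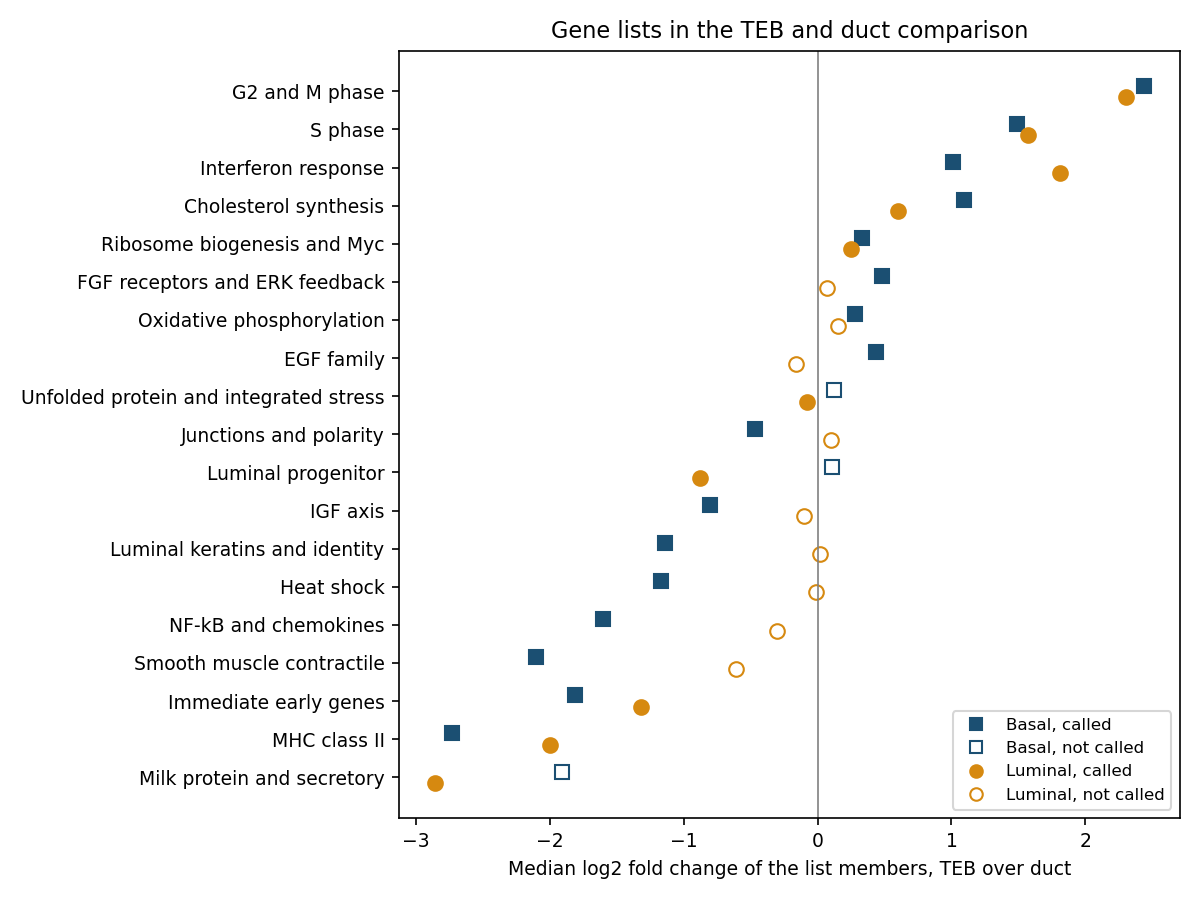
Median log2 fold change, TEB over duct, of the members of each gene list called in the basal gate (squares) or over the luminal gates (circles); filled symbols passed camera's test at a preset correlation. In both compartments the G2 and M phase list has the highest median (2.44 and 2.30), and the contractile list is at -2.10 in basal cells.

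The difference between the basal and luminal TEB effects was tested itself. It asked which changes of the TEB belong to a compartment. A total of 4761 genes differed, 2071 with a higher and 2690 with a lower log2 fold change in basal than in luminal cells. The cell cycle lists were not called (adjusted p = 0.69 for S phase and 0.496 for G2 and M phase). The contractile list changed more in basal cells (8 of 14 lower, 9 when adjusted over the list alone; adjusted p = 9.67e-07, and adjusted p = 0.287 with an estimated correlation). Cholesterol synthesis genes rose more in basal cells (10 of 18 higher, 12 when adjusted over the list alone; adjusted p = 7.21e-05, and adjusted p = 0.334 with an estimated correlation). Interferon response genes rose more in luminal cells (10 of 18 lower in the difference, 11 when adjusted over the list alone; adjusted p = 0.00158, and adjusted p = 0.551 with an estimated correlation), with Isg15 at log2 -1.03 ± 0.22. In basal cells alone 9 of these 18 rose and 3 fell, also adjusted over the list alone, with adjusted p = 0.0304 (0.099 without basal Elf5-model duct replicate 1, and adjusted p = 0.656 with an estimated correlation).

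Csn3 rose in basal TEB cells (log2 4.58) and fell in luminal ones (-2.19), a difference of 6.76 ± 0.51 (adjusted p = 4.87e-07). Kit rose in basal cells (3.47) and fell over the luminal gates together (-1.22, adjusted p = 0.013, and 0.0606 without the 2 libraries with keratinocyte transcripts), a difference of 4.70 ± 0.64 (adjusted p = 0.000114). Its duct and TEB means were 834 and 804 CPM in GFP-positive, 18.2 and 4.62 in GFP-negative, 97.5 and 21.2 in YFP-positive, and 2063 and 1292 in YFP-negative cells. Across the 10496 genes called in either compartment, which are not independent replicates, the TEB effects correlated at r = 0.355 (jackknife SE 0.057 over libraries; 0.261 over all genes). Of the genes called in both, 1975 were higher and 1685 lower in both, against 758 and 768 in independent lists. Another 297 and 452 moved in opposite directions, against 704 and 826.

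Each luminal gate was then compared between TEB and duct on its own, with 2 libraries per group, to ask which changes each population carries. In GFP-positive cells 4120 genes passed (2145 higher and 1975 lower), and 2099, 2610 or 2250 passed without TEB replicate 1, TEB replicate 2 or duct replicate 2. Of 24 S phase genes 21 rose, and all 24 G2 and M phase genes rose (22 and 24 when adjusted over each list alone; adjusted p = 1.2e-11 and 1.39e-11, and adjusted p = 0.516 and 0.525 with an estimated correlation). Of 18 interferon response genes 15 rose and 1 fell, also adjusted over the list alone (adjusted p = 1.72e-15, and adjusted p = 0.062 with an estimated correlation), with Isg15 at 49.3 ± 12.3 CPM in TEBs and 7.16 ± 0.460 in ducts. Milk genes fell (11 of 16, also adjusted over the list alone; adjusted p = 1.61e-05, and adjusted p = 0.361 with an estimated correlation), and Trf fell from 34320 ± 15440 to 3438 ± 650.4 CPM. Of 19 immediate early genes 16 fell (17 when adjusted over the list alone; adjusted p = 1.24e-21, and adjusted p = 0.0657 with an estimated correlation), and Fos was 7.56-fold lower (log2 -2.92 ± 0.27). Pgm5, a gene of the phosphoglucomutase family, was 228-fold lower (-7.84 ± 0.65).

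In GFP-negative cells 3351 genes passed (1603 higher and 1748 lower). That count was 1482 or 1422 without TEB replicate 1 or 2, 4258 without duct replicate 1, and 2308 without the 2 libraries with keratinocyte transcripts, of which 1701 were shared. It was 1179 with limma-voom and 105 in a fit of the GFP-negative groups alone. Of the 13 lists called in this gate, 8 kept their calls without the 2 libraries with keratinocyte transcripts. Of 18 interferon response genes 16 rose, also adjusted over the list alone (adjusted p = 2.53e-24), and the call held with an estimated correlation (adjusted p = 0.0264). Isg15 rose from 9.53 ± 0.409 to 71.8 ± 2.69 CPM. Of 24 S phase genes 14 rose and of 24 G2 and M phase genes 9 rose (24 and 23 when adjusted over each list alone; adjusted p = 6.64e-10 and 2.43e-09, and adjusted p = 0.484 and 0.509 with an estimated correlation). Milk genes fell (11 of 16, also adjusted over the list alone; adjusted p = 3.75e-10, and adjusted p = 0.113 with an estimated correlation). Of 19 immediate early genes 15 fell (17 when adjusted over the list alone; adjusted p = 1.4e-25, and adjusted p = 0.066 with an estimated correlation), and Fos was 9.28-fold lower (log2 -3.21 ± 0.27). Endothelial and pericyte markers summed to 40.7 and 54.2 CPM in TEBs and 22.5 and 30.7 CPM in ducts of this gate, although the list's median log2 fold change was -0.36. Ptprn rose 46.2-fold (5.53 ± 0.57). Dpysl2 stood at 3.40 ± 0.238 CPM in TEBs and had no count in ducts, so it was at least 80.8-fold higher. The basal genes Krt14 and Trp63 were among the most strongly lower (log2 -10.01 and -10.97), and without GFP-negative duct replicate 2, the library with keratinocyte transcripts, neither was called (-2.47, adjusted p = 0.224, and -2.75, adjusted p = 0.537). Without both libraries with keratinocyte transcripts the adjusted p was 0.0166 for Krt14 and 0.157 for Trp63.

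In YFP-positive cells 1424 genes passed (835 higher and 589 lower, 58.6% higher), and the share higher was 47.6% with DESeq2. Leaving out duct replicate 1 or 2 gave 473 or 816 genes, and leaving out TEB replicate 1 or 2 gave 464 or 668. DESeq2, limma-voom and a fit of the YFP-positive groups alone gave 2605, 3013 and 2424. Endothelial and pericyte markers summed to 50.4 and 46.8 CPM in TEBs and 11.6 and 15.5 CPM in ducts of this gate, with 1 of 14 genes higher, also adjusted over the list alone, and the list not called (adjusted p = 0.131). Of 24 G2 and M phase genes 20 rose and of 24 S phase genes 5 rose (23 and 20 when adjusted over each list alone; adjusted p = 3.84e-22 and 5.29e-13, and adjusted p = 0.324 and 0.438 with an estimated correlation). Of 18 interferon response genes 11 rose (13 when adjusted over the list alone; adjusted p = 6.05e-18, and adjusted p = 0.0831 with an estimated correlation), and Isg15 rose 3.64-fold (log2 1.87 ± 0.26). Elf5 fell from 82.6 ± 6.70 to 18.9 ± 5.51 CPM. Lactoferrin, Ltf, was 40.2-fold lower (-5.33 ± 0.83) and the synaptic vesicle gene Sv2c 12.1-fold higher (3.60 ± 0.55). Of 19 immediate early genes 5 fell (6 when adjusted over the list alone; median log2 fold change -0.35, adjusted p = 0.000217, and adjusted p = 0.613 with an estimated correlation).

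In YFP-negative cells 3341 genes passed (1898 higher and 1443 lower), and 1808 or 1769 passed without duct replicate 1 or 2, and 2162 or 2116 without TEB replicate 1 or 2. TEB replicate 2 of this gate is a library with keratinocyte transcripts; without it and the other such library 3010 genes passed, of which 2448 were shared, and 14 of the 17 called lists kept their calls. All 24 G2 and M phase genes and 18 of 24 S phase genes rose (24 and 22 when adjusted over each list alone; adjusted p = 1.31e-18 and 5.78e-11, and adjusted p = 0.337 and 0.464 with an estimated correlation). All 13 mitochondrially encoded genes rose, also adjusted over the list alone (median log2 fold change 0.77, adjusted p = 1.11e-09, and adjusted p = 0.337 with an estimated correlation), with mt-Co1 at 11790 ± 706.7 CPM in TEBs and 7860 ± 161.8 in ducts. Of 14 hormone-sensing genes 7 rose (8 when adjusted over the list alone; median log2 fold change 0.99, adjusted p = 0.000923, and adjusted p = 0.43 with an estimated correlation). Of 19 immediate early genes 15 fell, also adjusted over the list alone (adjusted p = 4.08e-13, and adjusted p = 0.337 with an estimated correlation). Ltf was 17.8-fold lower (log2 -4.15 ± 0.77) and Cck 22.0-fold lower (-4.46 ± 0.71). Endothelial and pericyte markers summed to 13.2 and 15 CPM in TEBs and 3.1 and 5.3 CPM in ducts of this gate. Fibroblast markers summed to 30.5 and 197.2 CPM in TEBs and 30.8 and 53.6 CPM in ducts.

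The TEB effects of the gates were compared with each other in the same model. Between GFP-positive and GFP-negative cells 1037 genes differed (443 higher and 594 lower in the difference), with 427, 553 or 666 without GFP-positive TEB replicate 1, TEB replicate 2 or duct replicate 2, and 572, 472 or 1898 without GFP-negative TEB replicate 1, TEB replicate 2 or duct replicate 1. The balance of directions turned over without GFP-negative duct replicate 1 (1027 higher and 871 lower) and with DESeq2 (1157 and 1078). Between YFP-positive and YFP-negative cells 504 genes differed (290 and 214). That count was 287 or 217 without YFP-positive duct replicate 1 or 2, 239 or 213 without YFP-positive TEB replicate 1 or 2, 259 or 200 without YFP-negative duct replicate 1 or 2, and 267 without YFP-negative TEB replicate 2. Here too the balance turned over, with 126 higher and 141 lower without YFP-negative TEB replicate 2, 103 and 114 without YFP-positive duct replicate 2, 294 and 381 without the 2 libraries with keratinocyte transcripts, and 754 and 756 with DESeq2. The mitochondrially encoded list was called in both differences. Its effect was higher in GFP-positive than in GFP-negative cells (7 of 13 genes, 13 when adjusted over the list alone) and lower in YFP-positive than in YFP-negative cells (4 of 13, 13 when adjusted over the list alone). The list had adjusted p = 1.77e-08 and 1.38e-11, and adjusted p = 0.444 and 0.354 with an estimated correlation. Immediate early genes fell less in YFP-positive than in YFP-negative cells (1 of 19 genes, 6 when adjusted over the list alone; adjusted p = 1.58e-05, and adjusted p = 0.731 with an estimated correlation), and the hormone-sensing list had a lower TEB effect in YFP-positive cells (medians -0.24 and 0.99; 2 of 14 genes lower, 4 when adjusted over the list alone; adjusted p = 1.58e-05, and adjusted p = 0.354 with an estimated correlation).

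The GFP-positive and GFP-negative comparison, over ducts and TEBs with 4 libraries each, asked what the cells of the Elf5-expressing luminal lineage express against the remaining luminal cells. GFP-positive cells expressed more luminal progenitor and milk genes, and GFP-negative cells more hormone-sensing genes, although no list kept its call with an estimated correlation. A total of 8291 genes passed, 4367 higher and 3924 lower in GFP-positive cells. All 14 luminal progenitor genes rose, also adjusted over the list alone (median log2 fold change 4.41, adjusted p = 9.29e-15, and adjusted p = 0.0598 with an estimated correlation). Elf5 was 28.3-fold higher (log2 4.82 ± 0.23) and the retinaldehyde dehydrogenase Aldh1a3 34.7-fold higher (5.12 ± 0.46). Kit stood at 818.7 ± 36.7 CPM in GFP-positive and 11.4 ± 14.2 CPM in GFP-negative cells, and its log2 fold change of 6.48 ± 0.61 became 7.59 without the 2 libraries with keratinocyte transcripts.

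Of 16 milk genes 15 rose, also adjusted over the list alone (median log2 fold change 6.63, or 6.26 with genes at 0 set to their bound; adjusted p = 2e-10, and adjusted p = 0.136 with an estimated correlation). Csn3 was 75.8-fold higher (6.24 ± 0.46) and Trf 90.2-fold higher (6.50 ± 0.39). Csn2 stood at 10520 and 1511 CPM in GFP-positive ducts and 141.7 and 64.51 CPM in GFP-positive TEBs. It stood at 62.9 and 55.25 CPM in GFP-negative ducts and 0.4357 and 0.5468 CPM in GFP-negative TEBs. In YFP-negative libraries it lay between 1.48 and 3.65 CPM, and the cause of this spread was not tested. Csn3 lay between 1722 and 9752 CPM in GFP-positive and between 1149 and 2289 CPM in YFP-negative libraries. Of 14 hormone-sensing genes 12 fell, also adjusted over the list alone (median -2.95, adjusted p = 1e-10, and adjusted p = 0.106 with an estimated correlation). Pgr was 8.87-fold lower in GFP-positive cells (-3.15 ± 0.31), the pioneer factor Foxa1 10.0-fold lower (-3.33 ± 0.29) and the oestrogen receptor Esr1 3.70-fold lower (-1.89 ± 0.16). Among the genes with the widest change, the alkaline phosphatase Alpl was 115-fold higher (6.85 ± 0.46). On the lower side, the uroplakin gene Upk3a was 30.7-fold lower (-4.94 ± 0.51) and Pthlh, parathyroid hormone-like hormone, 22.7-fold lower (-4.51 ± 0.37). The keratin Krt1 was lower by -7.10 ± 1.85, and not called without GFP-negative duct replicate 2 (adjusted p = 0.0562).

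The YFP-positive and YFP-negative comparison, with 4 libraries each, asked the same of the progesterone receptor lineage. YFP-positive cells carried the hormone-sensing programme and YFP-negative cells the luminal progenitor programme, the reverse of the GFP gates for these 2 lists. Here too no list kept its call with an estimated correlation. The milk gene Csn3 stood between 1149 and 2289 CPM in YFP-negative and between 9.96 and 125.9 CPM in YFP-positive libraries. Csn2 overlapped, between 1.48 and 3.65 CPM in YFP-negative and between 0.0692 and 8.04 CPM in YFP-positive libraries. A total of 9112 genes passed, 4488 higher and 4624 lower in YFP-positive cells. Of 14 hormone-sensing genes 13 rose, also adjusted over the list alone (median log2 fold change 4.07, adjusted p = 1.21e-13, and adjusted p = 0.059 with an estimated correlation). Pgr was 18.0-fold higher (log2 4.17 ± 0.33), Esr1 8.85-fold higher (3.15 ± 0.17), the EGF receptor ligand Areg 25.8-fold higher (4.69 ± 0.50) and the prolactin receptor Prlr 14.1-fold higher (3.82 ± 0.39). All 14 progenitor genes fell, also adjusted over the list alone (median -3.74, adjusted p = 2.58e-12, and adjusted p = 0.107 with an estimated correlation). Elf5 was 13.9-fold lower (-3.80 ± 0.22), Kit 35.8-fold lower (-5.16 ± 0.57) and Sox10 31.9-fold lower (-5.00 ± 0.51).

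Of 20 basement membrane genes, 12 fell and 4 rose in YFP-positive cells (13 and 4 when adjusted over the list alone; adjusted p = 0.00394, and adjusted p = 0.845 with an estimated correlation). The laminin chain Lama4 was 40.4-fold lower (-5.34 ± 0.31) and Col4a1 12.8-fold lower (-3.67 ± 0.26), whereas Lama5 was 3.67-fold higher (1.88 ± 0.16). Of 16 Wnt target genes 9 fell and none rose, also adjusted over the list alone (adjusted p = 0.00985, and adjusted p = 0.845 with an estimated correlation), and Axin2, a feedback regulator of Wnt signalling, was 6.66-fold lower (-2.74 ± 0.51). By the naming rule, the serotonin synthesis enzyme Tph1 was 35.1-fold higher (5.13 ± 0.36), the orphan nuclear receptor Esrrb 46.1-fold higher (5.53 ± 0.86) and Clca1 39.8-fold higher (5.32 ± 0.50).

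Across the 11059 genes called in the GFP or the YFP comparison, the log2 fold changes correlated at r = -0.721 (jackknife SE 0.124 over libraries; -0.594 over all genes). A total of 3154 genes were higher in GFP-positive and lower in YFP-positive cells, and 3018 the reverse, against 1115 and 972 in independent lists. Only 85 and 87 moved the same way, against 1082 and 1002.

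The basal and luminal comparison, with 8 and 16 libraries, asked what sets the layers apart and checked the gates. A total of 12255 genes passed, 6425 higher and 5830 lower in basal cells. All 14 contractile genes rose, also adjusted over the list alone (median log2 fold change 7.14), with Acta2 944-fold higher (log2 9.88 ± 0.12) and Myh11 802-fold higher (9.65 ± 0.17). All 14 luminal keratin and identity genes fell, also adjusted over the list alone (median -5.09), with Krt8 at 298.7 ± 125.3 CPM in basal and 3244 ± 1116 in luminal cells. Of 20 basement membrane genes 19 rose and 1 fell (Col4a1 254-fold higher, 7.99 ± 0.16), of 13 integrins 11 rose and 1 fell, and of 16 EMT genes 14 rose and 1 fell. Of 19 junction genes 17 fell and 1 rose (Cldn7 164-fold lower, -7.36 ± 0.17). These counts did not change when adjusted over each list alone.

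These 6 lists and the FGF receptor list kept their calls with an estimated correlation (adjusted p = 0.00371, 0.00224, 0.00387, 0.00558, 0.00563, 0.00224 and 0.0111). All 14 basal identity genes rose (adjusted p = 1.78e-05, and adjusted p = 0.332 with an estimated correlation), and 14 of 16 Wnt targets rose (adjusted p = 2.75e-06, and adjusted p = 0.159 with an estimated correlation), with Nkd1 357-fold higher (8.48 ± 0.24). Interferon response genes were lower in basal cells (16 of 18; adjusted p = 8.36e-07, and adjusted p = 0.159 with an estimated correlation). Reln, a secreted glycoprotein, stood at 904.1 ± 365.3 CPM in basal and 0.428 ± 0.407 CPM in luminal cells. Fibroblast markers were also higher in basal cells (13 of 14 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.00576, and adjusted p = 0.607 with an estimated correlation), with Col1a1 at 92.2 ± 67.4 and 9.76 ± 8.11 CPM.

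The basal cells of both mouse models were compared, with 4 libraries each, to see what the models themselves contribute. A total of 1808 genes passed, 823 higher and 985 lower in the Elf5 model, and 1165 passed without basal Elf5-model TEB replicate 2. Elf5 was 12.7-fold higher in the Elf5 model (log2 3.67 ± 0.24), at 22.1 ± 5.37 CPM against 1.81 ± 1.05. Padi3 was 41.8-fold higher (5.39 ± 0.23), the transcription factor Sox11 46.0-fold higher (5.52 ± 0.37) and Pianp 24.7-fold higher (4.63 ± 0.23). The ribosomal protein genes Rpl29 and Rps2, which have processed copies that share reads, were 20.1-fold lower (-4.33 ± 0.10) and 13.1-fold lower (-3.71 ± 0.11). No list beyond EMT, endothelial and contractile genes was called, and these had 3 of 16 genes higher, 3 of 14 higher and 3 of 14 lower. Adjusted over each list alone, 5 endothelial and 5 contractile genes passed. With an estimated correlation the adjusted p was 0.182, 0.651 and 0.979.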

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

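The tests of basal mammary cells, of handling, of strain variants and of mapping settings were chosen after the results were seen, as was the fit without the 2 libraries with keratinocyte transcripts.

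In GFP-negative duct replicate 2 and YFP-negative TEB replicate 2, keratinocyte genes summed to 3088.1 and 619.7 CPM. A second list of keratinocyte genes had 15 of 28 measured genes at least 2-fold above the highest of the 14 other luminal libraries in GFP-negative duct replicate 2, and 6 of 28 in YFP-negative TEB replicate 2. Basal mammary cells are argued against, since the median contractile gene reached 0.6% and 0.7% of the level that the Krt14 share (34.07% and 51.23%) predicts, with 86.5 against 11340.5 and 328.7 against 5277.5 summed CPM. RNA of skin keratinocytes may therefore be present in the first library, with Krt5 at 1962 and Krt10 at 990.9 CPM, although Krt6a and Sprr1a of the second list reached 534 and 192 CPM in other luminal libraries and the EpCAM gate would remove cells without EpCAM. No biological explanation was tested.

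Immediate early genes were lower in TEBs in the basal gate and in the 4 luminal gates, with median log2 fold changes of -1.81, -1.65, -1.89, -0.35 and -1.28 (basal, GFP-positive, GFP-negative, YFP-positive and YFP-negative), where 16, 16, 15, 5 and 15 of 19 genes fell (16, 17, 17, 6 and 15 adjusted over the list alone) and adjusted p = 0.165, 0.0657, 0.066, 0.613 and 0.337 with an estimated correlation. A bias by genomic span is argued against over the luminal gates together, and was not tested in the basal gate. A set of 462 genes matched in span and level had a median of -0.04 (quartiles -0.38 and 0.24), against -1.32 for the list over the luminal gates. The match was loose, with a median span of 6160 bases against 4258 for the list. Transcript length was not matched, so a bias by transcript length was not tested. Handling or dissociation that differed between ducts and TEBs cannot be told apart from a tissue difference, because tissue and dissection coincide in every library and the heat shock list, also induced by dissociation, had a median below 0 in 3 of 5 populations (-1.17, -0.27, -0.21, 0.18 and 0.05). A difference between the tissues themselves stays open and was not tested apart from it.

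Between the models, 1808 genes differed in the basal gate, among them Rpl29 and Rps2 at 6.47 to 13.5 and 21.5 to 36.9 CPM over the 12 libraries of the Elf5 model, against 149 to 224 and 374 to 488 over the 12 of the PR-cre model. Mapping or counting settings that shift ribosomal protein genes as a set are argued against, as the 74 genes had a median absolute log2 fold change of 0.09 (8 lower, 1 higher, 65 not called). This median cannot decide the cause of the 1808 differences, since a cause that touches few genes would leave it near 0. Such settings stay open for them, among them the 4 over 4-fold lower (Rpl29, Rps2, Rpl34 at -2.88 and Rps18 at -2.37, without overlap between the models over 12 libraries each). Over the 1808 genes, the model changes correlated at r = -0.014 with the GFP-positive against GFP-negative changes. That comparison separates luminal populations and not levels of Elf5 within basal cells. It therefore cannot decide whether Elf5 from the reporter allele contributes. Strain variants against the reference may contribute: genes of the H2 region of chromosome 17 were called over 2-fold more often than others (22 of 139 against 645 of 17970, odds ratio 5.05, 95% exact interval 3.03 to 8.07, Fisher p = 7.64e-09), against 1.63 (1.07 to 2.43) in the basal TEB comparison. The Fisher test treats genes as independent, whereas neighbouring genes can vary together, so its intervals may be too narrow and its p too low. It also did not account for other cell types. In basal ducts the immune list summed to 42.5 and 26.2 CPM in the Elf5 model and 17.6 and 20.6 in the PR-cre model. The endothelial and pericyte list summed to 157.5 and 93.7 against 33.2 and 41.8 CPM. Housing, age and the batches in which the models were prepared are not given and were not tested.

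TEB effects differed between groups by a test of the difference itself, for 4761 genes between basal and luminal cells, 1037 between GFP-positive and GFP-negative cells and 504 between YFP-positive and YFP-negative cells. For basal minus luminal the widest differences on the log2 scale were Csn3 6.76, Apod 6.32, Fut9 5.32 (6.55 without GFP-negative TEB replicate 2), Efhd1 5.20 (4.42 without GFP-negative duct replicate 2) and Adam23 5.05. The lowest were Slpi -8.05, Pcp4 -7.69 (-10.31 without GFP-negative duct replicate 1), Thsd7a -6.53, Pamr1 -6.11 (-6.76 without the 2 libraries with keratinocyte transcripts) and Tmem200a -5.86. The value of Tmem200a depends on the prior count, since it had no count in GFP-positive and YFP-positive ducts (28.4 CPM at most in basal TEBs and 103.4 at most in basal ducts). Adam23 was not called without GFP-positive duct replicate 1, nor Tmem200a without GFP-positive TEB replicate 1 or YFP-positive TEB replicate 2 (adjusted p = 1 each, with a group then at 0).

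For GFP-positive minus GFP-negative cells they were Trp63 12, Bcl11b 11.12, Krt14 10.66, Arsi 9.07 and Lmo1 8.99, and without GFP-negative duct replicate 2 none of these 5 was called (adjusted p = 0.472, 0.373, 0.252, 1 and 0.599). Of the 8 libraries, 7 ended the calls of Trp63, Bcl11b, Krt14 and Lmo1 when left out, and GFP-negative TEB replicate 2 that of Arsi as well. On the other side were Dpysl2 at a fitted -7.80, which depends on the prior count (21.2 and 4.35 CPM in GFP-positive TEBs and ducts, 3.40 and 0 in GFP-negative ones), Colgalt2 -5.58 (adjusted p = 0.155 without GFP-negative TEB replicate 2), Ggt5 -4.52 (-3.70 without GFP-positive duct replicate 1), Itgb3 -4.18 (-5.67 without GFP-negative duct replicate 2) and C3 -4.06, whose call ended without any 1 of the 8 libraries (adjusted p up to 0.121).

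For YFP-positive minus YFP-negative cells they were Itgb3 4.14, Ptprn 3.78, Scnn1b 3.28, Thsd7a 3.22 and Ramp1 3.20, and Abcc4 at a fitted -7.74, which depends on the prior count (3.45 and 2.62 CPM in YFP-positive TEBs and ducts, 0.889 and 0 in YFP-negative ones), Camk1d -5.96 (-8.49 without YFP-negative duct replicate 2), Tnfrsf11b -5.29, Fras1 -5.08 and Aqp3 -4.53. The calls of Scnn1b, Ramp1, Abcc4 and Camk1d held without any 1 library. The others were lost without at least 1 library, with adjusted p up to 0.0733 for Itgb3 (YFP-negative TEB replicate 2), 0.0743 for Ptprn and 0.0519 for Thsd7a (both YFP-positive duct replicate 1), 0.0656 for Tnfrsf11b (YFP-negative duct replicate 1), 0.183 for Fras1 (YFP-positive duct replicate 2) and 0.216 for Aqp3 (YFP-negative TEB replicate 2).

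In other splits of the libraries into groups of the same sizes, each fitted alone, the real split called the most genes for 5 of 7 counts. At most 100 splits were drawn per count. Most other splits mix tissues, models or gates within a group, which widens the spread, so few calls would be found there in any case. They therefore cannot exclude chance differences between animals or preparations. The real split was the highest for basal TEB (6501 genes against 126 for the highest of the other 34 splits, the split by model), luminal TEB (1720 against 20, 1 of 100), GFP (4308 against 27, 1 of 35), YFP (6729 against 312, 1 of 35) and basal against luminal (9357 against 3910, 1 of 100). For the model comparison 2 of 35 splits called as many genes (126, and 6501 for the split by tissue, a structure of the samples). The remaining splits called 0 genes. Because the split by tissue exceeds that by model in any case, this count could not have excluded chance. Of 305 genes over 4-fold different between models in basal cells, 250 (82%) went the same way between GFP-positive and YFP-negative cells, 166 of them called. Between GFP-negative and YFP-positive cells 254 (83.3%) did, 148 of them called. These are separate libraries, but the labels do not say that they came from other animals than the basal libraries. The shared direction therefore does not exclude chance differences between animals or preparations. For the basal minus luminal difference, 6 of 100 splits called as many genes (861, highest other 2737). There the tissue labels were regrouped within each compartment. Such a regrouping can keep the real split of the basal libraries, and with it the basal TEB effect. The count of splits therefore cannot decide, and chance was not excluded there either.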

How the results depend on the processing

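The fit without the 2 libraries with keratinocyte transcripts and the mixed fry test were chosen after the results were seen. Of 315 alternative values of 16 results (13 counts of genes called, the count of lists called and 2 correlations), 269 stayed within the limits set for them, 46 moved and 0 reversed. The counts for basal TEB (6685 to 7590 without 1 library), luminal TEB (6192 to 7474), GFP (7223 to 8383), YFP (8111 to 8621), basal against luminal (11728 to 12463) and the basal minus luminal difference (3874 to 5626) stayed within 1.5 times under every alternative run. Whether more genes were higher or lower turned over under at least 1 alternative for each of the 13 counts except that between models. Leaving out 1 library gave 2099 to 3195 genes in GFP-positive, 1422 to 4258 in GFP-negative, 464 to 816 in YFP-positive and 1769 to 2162 in YFP-negative cells, 427 to 1898 and 200 to 336 for the GFP and YFP differences, and 1165 to 1558 between models; these fits hold fewer samples, and a lone library is assumed to vary like the other groups. With DESeq2 the count was 2605 in YFP-positive cells, 2235 and 1510 for the GFP and YFP differences and 2835 between models; with limma-voom it was 1179 in GFP-negative and 3013 in YFP-positive cells, 523, 986 and 2753. Fitting only the groups compared gave 105 in GFP-negative and 2424 in YFP-positive cells, 153 and 1172, and the fit without the keratinocyte libraries gave 2141 in YFP-positive cells. Of 387 list tests, 104 passed camera, 9 passed with an estimated correlation, 202 passed fry and 351 its mixed test. Over all genes the correlations were -0.594 and 0.261. The cause of these moves was not tested. Of 378 gene results, the call and direction were kept for 374 with DESeq2, 377 with RLE scaling, 368 with a replicate block and 357 without the keratinocyte libraries. Without 1 library in turn, 4127 gene values kept both, 198 were no longer called, 6 became called and 1 moved. Libraries with the same replicate number had weakly correlated deviations from their group means (30 pairs of groups, correlations from -0.001 to 0.126, median 0.039). A weak pairing by preparation is therefore not excluded, and with the replicate block 8081 genes passed in basal TEB. Depth limits genes near 0.058 to 0.097 CPM, the level of 3 counts.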

Other observations

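The gene lists were fixed beforehand, and the groupings in this part were chosen after the results were seen. Mitochondrially encoded genes were lower in GFP-positive than in GFP-negative cells (13 of 13, also adjusted over the list alone; median log2 fold change -0.64, adjusted p = 0.000738, and adjusted p = 0.859 with an estimated correlation), with mt-Co1 at 10120 and 14260 CPM. The Wnt ligand and receptor list was not called between the luminal fractions (6 of 21 higher and 7 lower in GFP-positive cells, 7 and 7 adjusted over the list alone, adjusted p = 0.386; 8 higher and 6 lower in YFP-positive cells, also adjusted over the list alone, adjusted p = 0.615). Among its members, picked after their values were seen, Wnt4 and Wnt5a were 10.4-fold and 11.6-fold lower in GFP-positive cells and 18.9-fold and 22.5-fold higher in YFP-positive cells, and Wnt5b was 30.4-fold lower in YFP-positive cells. Fatty acid synthesis genes were higher in GFP-positive cells (11 of 16, with 2 lower, also adjusted over the list alone; adjusted p = 0.00181, and adjusted p = 0.566 with an estimated correlation), with Fads1 37.1-fold and Fads2 42.2-fold higher. In GFP-negative TEB cells, 10 of 20 glycolysis and hypoxia genes were higher (14 when adjusted over the list alone; adjusted p = 1.11e-06, and adjusted p = 0.368 with an estimated correlation).

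Fibroblast markers summed to between 638.4 and 1627.8 CPM in basal and between 30.5 and 819.8 CPM in luminal libraries. Adipocyte markers summed to between 35.1 and 89.4 CPM in basal ducts and between 10.5 and 17.9 CPM in basal TEBs. Schwann cell markers summed to 151.6 and 165.5 CPM in YFP-negative ducts and 89.2 and 89.9 CPM in YFP-negative TEBs.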
